A study of Rattus norvegicus with 12 samples.

How the data were processed

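RNA from TRL1215, a line of rat liver epithelial cells, was measured on 12 Affymetrix rat expression arrays. The labels describe 4 groups of 3 arrays each: passage-matched controls without added compound, and cells kept in perfluorooctanoic acid (PFOA, a fluorinated surfactant). The exposed groups are T10, T50 and T100, named for their dose of 10, 50 and 100 µM. Exposure lasted up to 38 weeks, with weekly passage; the week at which each sample was taken is not given in the sources used here. The labels name the WT Plus amplification and labelling kit and 100 ng of input RNA. They do not say whether the 3 replicates of a group were separate long-term cultures, so every p-value measures only the spread between these samples.

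The deposited values are on a log2 scale, with 1 value per probe set and array. They ran from 2.87 to 19.93, a ceiling shared by many probe sets, and the log base was inferred from that range. How the authors corrected for background, summarized probes and normalized the arrays is not given in the sources used here. The medians of the 12 arrays over all probe sets lay in a narrow band between 3.73 and 3.81. The 95th percentile over genes ranged from 9.36 on T10 replicate 1 to 9.74 on T100 replicate 3. The mean 95th percentile was 9.57 in control, 9.42 in T10, 9.57 in T50 and 9.66 in T100.

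The table held 70580 probe sets, of which 1738 were controls, 23446 carried exactly 1 gene symbol in the platform's annotation, 505 carried several and 44891 carried none. Of the 23446 probe sets with 1 symbol, 22077 were matched through the Entrez number to the rat gene table, which renamed 1, and the others kept the symbol of the annotation. Where a gene had several probe sets (1182 genes), the one with the highest mean over the 12 arrays was used, which left 22093 genes. No genome coordinates were used. A gene was called above background in a group when its mean exceeded the 95th percentile of the 1153 negative-control probe sets there. That level, averaged over the arrays, was 5.42 in control, 5.77 in T10, 5.52 in T50 and 5.65 in T100. This held for 4581 genes (20.7%) in at least 1 group, while dim genes stayed in the tests. For 160 genes the value was identical on all 12 arrays, 48 of them at the ceiling and 112 below it, and 852 genes held 1 value on 3 or more arrays. Among the 511 genes with a mean over 12, 368 were of that kind, so changes in the brightest genes can be hidden.

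Differences were tested with limma 3.58.1 in R 4.3.3. lmFit and eBayes were run on all 12 arrays with the 4 group means as the model, so that each group of 3 shared 1 estimate of the spread (prior degrees of freedom 1.71). No block was fitted, because the shared replicate numbers are not said to mark a common culture or day. Contrasts set each exposure against control, each pair of exposures against each other, and the ordered groups against a trend with weights of -3, -1, 1 and 3; a moderated F test asked for any difference among the 4 groups. All p-values were two-sided and were adjusted by Benjamini-Hochberg over all 22093 genes, and a gene was called at an adjusted p under 0.05. A second count asked also for a change of at least 2-fold. Errors of log2 changes are the standard errors of the fit, with n = 3 arrays in each group. The number of arrays limits the precision.

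The 30 gene lists, all comparisons and the tests were fixed before the data were examined. Lists were tested with camera at a preset correlation of 0.01, two-sided, with Benjamini-Hochberg over the lists. Camera with an estimated correlation and fry, which asks whether a list's genes move 1 way on balance, were run beside it. The last 3 lists hold markers of other liver cell types. The named genes followed a rule set at the same time. Against control, it took the 8 called genes with the largest rise and the 8 with the largest fall, among genes whose 3 exposed arrays all lay on 1 side of the 3 controls and whose symbol was not a provisional one. Between exposures and for the trend it took 4 of each, with the 4 means in order of dose for the trend. It added up to 4 called members of each list described, or up to 2 with the smallest p where none was called, and 12 genes of interest. Some other genes of interest are not reported here. Genes named outside the rule are said to be so.

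The same steps were tested on simulated data with changes placed in known genes. These were drawn only from brighter genes whose values varied within groups, so recovery among dim genes was not tested. At a log2 change of 0.5 they recovered 47.8% of such genes for T10, 47.8% for T50 and 50.7% for T100, and at a change of 1 they recovered 88.1%, 92.5% and 92.5%. False calls made up 3.11%, 11.1% and 4.73% of all calls. Camera called 0 of the simulated unchanged lists, beside a shifted list that it found. The simulated genes varied independently, so this does not show how often camera calls unchanged lists whose genes vary together. In the data the estimated correlation was 0.355 for the list of G2 and mitosis. Sharing between exposures was set against 50 simulations of unchanged groups with common controls, since 3 controls cannot be divided into separate sets for each exposure.

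Alternatives covered filters on dim genes, scaling of the arrays by quantiles or by medians, the handling of several probe sets per gene, all probe sets whether named or not, the variance model, array weights, a replicate block, each array left out in turn, and fits of 6 arrays. Added after seeing the data were 3 more: genes with held values left out, the 95th percentile of each array as a covariate, and both arrays at the ends of that range left out. Figures were drawn with Python 3.11.15 and matplotlib 3.10.9.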

Results

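Expression of 22093 genes was measured on 12 arrays of the rat liver epithelial line TRL1215, 3 each for passage-matched control cells and cells kept in PFOA at 10, 50 or 100 µM for up to 38 weeks. The title of the series concerns tumour-cell traits gained by these cells under chronic PFOA, and the comparisons ask which genes differed from control after each exposure. Hepatocyte genes were near background. Of 38 hepatocyte markers measured, 2 were above background in any group and 0 were called by limma against control, where 2778, 2325 and 2733 of all genes had an unadjusted p under 0.05 at T10, T50 and T100.

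Arrays of 1 group lay nearer to each other than to those of other groups. Pairs within a group had a root mean square difference of 0.126 to 0.173 log2 units over all genes, and pairs across groups 0.169 to 0.268. The first principal component (25.7% of the variance) ran from T10 (-17.9 to -6.44) through control (-2.76 to -2.16) and T50 (-0.116 to 3.73) to T100 (8.67 to 18.8). The same order, apart from control and T50 being level, was seen in the 95th percentile of the values, which was 9.42 in T10, 9.57 in control and T50, and 9.66 in T100. The second component (17.5%) set control and T50 apart from T10 and T100. The mean 95th percentile of the negative controls was also lower in control (5.42) and T50 (5.52) than in T10 (5.77) and T100 (5.65). T100 replicate 1, at 5.48, lay among the control and T50 arrays. Whether background contributes to this component was not tested.

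**Figure D1:**
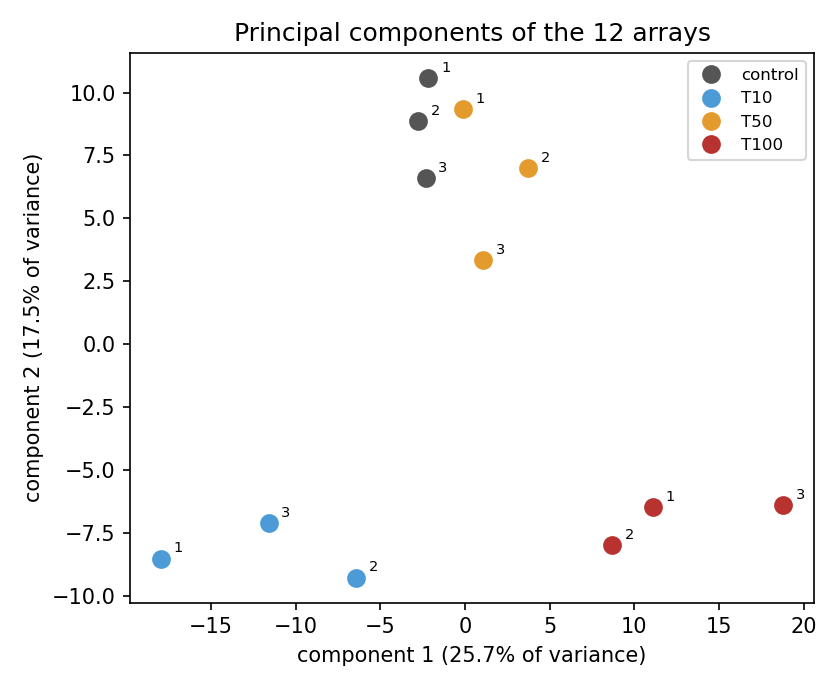
Scores of the 12 arrays on principal components 1 (25.7% of the variance) and 2 (17.5%) of the gene values, with points coloured by group and numbered by replicate. The 3 arrays of each group lie together, with T10 at the left and T100 at the right of component 1.

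At 10 µM an amino acid transporter gene was among the largest rises and the inducible cyclooxygenase gene among the largest falls. Slc7a8, a transporter of neutral amino acids, rose by 2.68 ± 0.13 log2 units (SE, n = 3 and 3; 6.39-fold; adjusted p = 2.10e-05). Ptprz1, a receptor-type tyrosine phosphatase, rose from below background in control cells (3.96 ± 0.09, SD) to 6.43 ± 0.08 (adjusted p = 1.44e-07), so its fold is not given. Ptgs2, the inducible cyclooxygenase, changed by -3.15 ± 0.16 (8.89-fold lower; adjusted p = 2.10e-05). Tex101, a surface glycoprotein best known from germ cells, changed by -3.71 ± 0.15 and was 13.1-fold lower, and Fgf19, a growth factor of the endocrine family that controls bile acid synthesis, changed by -3.67 ± 0.31.

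Among the other large changes at 10 µM, the calcium sensor Vsnl1 rose by 1.65 ± 0.23 and the metalloprotease Adam12 by 1.07 ± 0.18, beside Cux1-ps1 (1.68), Tmem45a (1.32, in no group above background), Fam25a (1.00) and Nptx1 (0.88). The chemokine Ccl7, which attracts monocytes, changed by -2.67 ± 0.17, the oxygen-sensing prolyl hydroxylase Egln3 by -2.73 ± 0.30, the NKG2D ligand gene Ulbp1 by -2.54 ± 0.33, the smooth-muscle actin Acta2 by -2.21 ± 0.30 and the interleukin-1 receptor antagonist Il1rn by -2.05 ± 0.22. Without single arrays the calls of 5 of these 16 genes ended. The adjusted p reached 0.0567 for Vsnl1, 0.104 for Adam12 and 0.122 for Nptx1 without control replicate 2, 0.0639 for Fam25a without control replicate 1, and 0.0548 for Acta2 without T10 replicate 1. With the 95th percentile of each array as a covariate, chosen after seeing the data, Egln3 (adjusted p = 0.214), Ulbp1 (0.339) and Il1rn (0.178) were not called either, nor were Vsnl1, Fam25a, Nptx1 and Acta2. A second probe set of Ulbp1 was at -0.91. Fgf19, Ulbp1 and Il1rn were below background at 10 µM, so the size of their falls is uncertain.

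Some inflammatory cytokine genes and NF-kB targets were lower at 10 µM. Of 39 measured members, 5 fell, 1 rose and 33 did not pass, or 8 and 2 when adjusted over the list alone. Only 11 of the 39 were above background in any group. Ptgs2, Ccl7 and Il1rn were among those that fell, and the list passed camera (mean -0.30, adjusted p = 0.00356, and adjusted p = 0.208 with an estimated correlation). The median change was only -0.05, with 25 members lower and 14 higher, so the mean rests largely on a few large falls. Of 28 p53 targets, 2 fell (Eda2r, a receptor of the tumour necrosis factor family, -1.07 ± 0.19, and the death receptor gene Tnfrsf10b, -0.30 ± 0.05, below background) and 26 did not pass, or 9 that fell and 1 that rose when adjusted over the list alone. That list also passed camera (mean -0.19, adjusted p = 2.99e-05; adjusted p = 0.485 with an estimated correlation). Of 38 genes of G2 and mitosis, 2 fell (Birc5, -0.43 ± 0.07, and the checkpoint kinase Bub1, -0.34 ± 0.06) and 36 did not pass, or 7 that fell when adjusted over the list alone (camera adjusted p = 3.09e-06; adjusted p = 0.494 with an estimated correlation).

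Of 30 TGF-beta and YAP targets, 1 fell at 10 µM (Tgfb3, a TGF-beta ligand, -0.45 ± 0.08), or 3 when adjusted over the list alone, and 29 did not pass (camera mean -0.12, adjusted p = 0.00576; adjusted p = 0.494 with an estimated correlation). Of 38 tumour suppressors and oncogenes, 0 were called, or 1 that was lower when adjusted over the list alone; Myc was at -0.43 ± 0.08 with an adjusted p of 0.0553, and the list passed camera (mean -0.07, adjusted p = 0.0480; adjusted p = 0.494 with an estimated correlation). After quantile normalization the lists for mitosis (adjusted p = 0.765), TGF-beta and YAP targets (0.271) and tumour genes (0.648) no longer passed. Nor were their members Bub1 (-0.15, adjusted p = 0.384), Birc5 (-0.30, 0.164) and Tgfb3 (0.0519) called, or the p53 targets Eda2r (0.0519) and Tnfrsf10b (0.0768). After the 95th percentile was added as a covariate, chosen after seeing the data, the lists for p53 targets (adjusted p = 0.814), mitosis (0.974), TGF-beta and YAP targets (0.890) and tumour genes (0.802) did not pass either. The list of tumour genes also lost its call in fits without control replicate 2 or 3, T10 replicate 1 or 3, T50 replicate 2 or 3, or T100 replicate 3, with a mean of -0.04 and an adjusted p of 0.206 without T10 replicate 1. The calls of Eda2r, Tnfrsf10b, Birc5, Bub1 and Tgfb3 ended without single arrays, at adjusted p of up to 0.144 (control replicate 2), 0.134, 0.0968 and 0.103 (control replicate 1) and 0.149 (control replicate 2). The arrays at 10 µM had the lowest 95th percentile of values (9.42, against 9.57 in control), beside these lists of lower genes.

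In all, 192 genes were called at 10 µM against control, 34 higher and 158 lower on the deposited values, and 120 higher and 121 lower after quantile normalization. At least 2-fold changes were found for 7 higher and 27 lower genes, and 119 of the 192 were above background in a group. The count was 84, 73 or 116 without control replicate 1, 2 or 3, 67 without T10 replicate 1 and 114 without T10 replicate 3. With the 95th percentile of each array as a covariate, an alternative chosen after seeing the data, it was 15, 8 higher and 7 lower. The count of 2-fold changes went from 34 to 22 without control replicate 2.

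**Figure D2:**
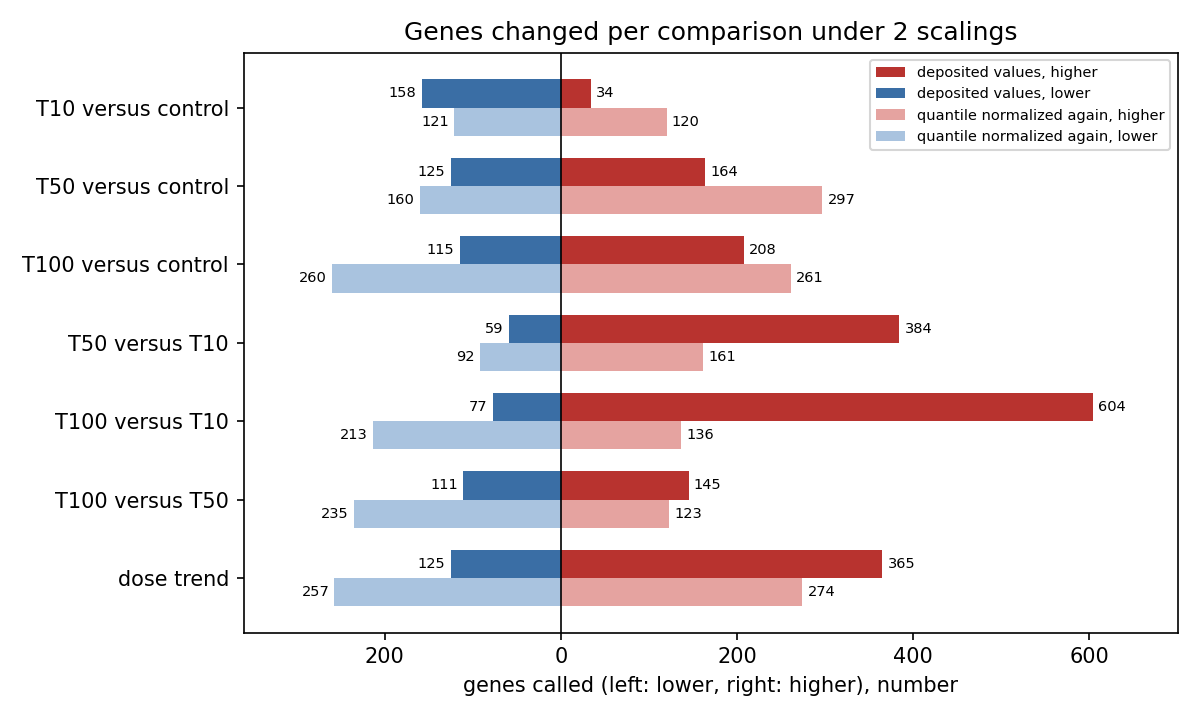
Number of genes called higher (right) and lower (left) in each comparison and for the dose trend, with dark bars for the deposited values and light bars for the same values quantile normalized again. At T10 against control the split is 34 to 158 with the deposited values and 120 to 121 after quantile normalization.

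At 50 µM a tight-junction gene, an ion channel and a laminin chain were among the largest rises. Cldn1, a sealing protein of tight junctions, rose by 1.98 ± 0.16 (3.94-fold; adjusted p = 0.000551), and Ano1, a calcium-activated chloride channel, by 1.53 ± 0.11. Ano1 was below background in control, so the size of its rise is uncertain. Lama2, which encodes a laminin chain of basement membranes, rose from below background in control (3.79 ± 0.06, SD) to 5.78 ± 0.34 (adjusted p = 0.000267), so its fold is not given. Tex101 was again the largest fall, at -4.43 ± 0.15 (21.5-fold lower; adjusted p = 2.12e-06). Abcb1b, which encodes a P-glycoprotein that pumps drugs out of cells, changed by -1.71 ± 0.24 (3.26-fold lower; adjusted p = 0.00994).

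Further rises at 50 µM were those of the complement receptor gene C3ar1 (1.40 ± 0.28), Adam12 (1.31 ± 0.18), Cbx3l1 (1.22 ± 0.14), the cytokine gene Il24 (1.15 ± 0.14, from below background) and Frmd4b (1.15 ± 0.21). Further falls were those of Il1rn (-1.73 ± 0.22), Cpxm2 (-1.66 ± 0.12, to below background), the laminin receptor gene Bcam (-1.53 ± 0.16), Ccl7 (-1.30 ± 0.17) and follistatin, Fst, which binds activin (-1.25 ± 0.08). Without control replicate 2 the adjusted p of C3ar1 was 0.159, and without T50 replicate 2 that of Frmd4b was 0.119; the other 14 of the 16 largest changes kept their calls without each array.

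The p53 targets were lower at 50 µM: 7 of 28 measured members fell, 0 rose and 21 did not pass, or 13 that fell and 1 that rose when adjusted over the list alone. Eda2r changed by -1.65 ± 0.19, the sulfatase gene Sulf2 by -0.62 ± 0.08, the cyclin gene Ccng1 by -1.01 ± 0.15, and Mdm2, which encodes the ubiquitin ligase that restrains p53, by -0.71 ± 0.14. The list passed camera (mean -0.24, adjusted p = 2.42e-08; adjusted p = 0.152 with an estimated correlation). Without T50 replicate 2 the adjusted p of Ccng1 was 0.0657, and without control replicate 1 that of Mdm2 was 0.156. Cdkn1a, the classic p53 target that encodes a cell cycle inhibitor, was below background in all 4 groups (3.89 ± 0.05, SD, in control).

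Of 39 inflammatory and NF-kB genes, 3 fell at 50 µM (Il1rn, Ccl7 and the macrophage growth factor Csf1, -0.99 ± 0.15), 1 rose (Tnfaip3, an inhibitor of NF-kB that was below background, 0.44 ± 0.07) and 35 did not pass, or 5 and 2 when adjusted over the list alone. The list passed camera (mean -0.13, adjusted p = 0.0230, and adjusted p = 0.152 with an estimated correlation). Its median change was -0.02, with 24 members lower and 15 higher. Of 28 genes of xenobiotic metabolism (5 above background in a group), 2 fell and 26 did not pass, or 3 that fell when adjusted over the list alone. Both that fell were efflux pumps, Abcb1b and Abcb1a (-0.37 ± 0.07, below background), and the list passed camera (adjusted p = 0.0337; adjusted p = 0.369 with an estimated correlation). The adjusted p of Csf1 and Abcb1a reached 0.0720 and 0.121 without control replicate 2, and that of Tnfaip3 reached 0.0877 without T50 replicate 2. The inflammatory list lost its call without T50 replicate 3 (adjusted p = 0.0679), and the xenobiotic list without control replicate 1 or 2, T10 replicate 2 or 3, or T50 replicate 3, at adjusted p of up to 0.113.

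Hypoxia and glycolysis genes included 3 of 38 that fell at 50 µM and 0 that rose, or 4 that fell when adjusted over the list alone: the peptide hormone Adm (-0.85 ± 0.14, below background), the glycolytic enzyme Pfkl (-0.74 ± 0.14) and the mitophagy receptor Bnip3l (-0.35 ± 0.07). Of 35 epithelial junction genes, Cldn1 rose, while Jup (plakoglobin, -0.83 ± 0.15) and Lamb3 (a laminin chain of epithelial anchorage, -0.77 ± 0.12) fell and 32 did not pass, or 1 and 5 when adjusted over the list alone. Only 9 of these 35 were above background in any group. Camera gave adjusted p of 0.0230 for hypoxia and 0.0406 for junction genes; with an estimated correlation the adjusted p = 0.375 and adjusted p = 0.152, and after quantile normalization neither list passed. Without single arrays the adjusted p reached 0.0693 for Adm (T50 replicate 2), 0.138 for Pfkl (control replicate 1), 0.141 for Bnip3l (T50 replicate 3), 0.110 for Jup (control replicate 2) and 0.0633 for Lamb3 (control replicate 1). The hypoxia list lost its call without control replicate 1 or T50 replicate 3, at adjusted p of up to 0.136, and the junction list without control replicate 2, any T10 replicate, or T50 replicate 1 or 2, at up to 0.125.

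At 50 µM 289 genes were called against control, 164 higher and 125 lower, 182 of them above background in a group; quantile normalization gave 457, 297 higher and 160 lower. At least 2-fold changes were found for 11 higher and 13 lower genes. The count was 128, 117 or 153 without control replicate 1, 2 or 3, 181 or 120 without T50 replicate 1 or 2, and 179 without T100 replicate 1.

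At 100 µM the matrix genes Eln, Col1a1 and Col12a1 and the smooth-muscle actin gene Acta2 were among the largest rises. The tropomyosin gene Tpm2 and the collagen gene Col8a1 were among the largest falls. Eln, which encodes elastin, rose by 3.88 ± 0.51 (14.7-fold; adjusted p = 0.00919), from 9.03 ± 0.13 to 12.91 ± 1.00 (SD). Col1a1, a chain of type I collagen, rose by 2.36 ± 0.29 (5.14-fold; adjusted p = 0.00712), Col12a1 by 1.69 ± 0.27 and Acta2 by 2.04 ± 0.30 (4.11-fold; adjusted p = 0.0134). Car9, a cell-surface carbonic anhydrase induced in hypoxia, rose by 2.24 ± 0.30 (4.73-fold; adjusted p = 0.0102). Ccl7 changed by -3.15 ± 0.17 (8.86-fold lower; adjusted p = 0.000124) and Fgf19 by -3.15 ± 0.31.

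Other rises at 100 µM were those of Dsel (2.12 ± 0.24), the integrin gene Itgb8 (2.01 ± 0.32) and F3, which encodes tissue factor (1.75 ± 0.24). Other falls were those of Tnfrsf22 (-2.05 ± 0.40), Tex101 (-1.99 ± 0.15), Egln3 (-1.57 ± 0.30), the tropomyosin gene Tpm2 (-1.45 ± 0.21), Col8a1, a collagen of short chains (-1.43 ± 0.16), and Il1rn (-1.43 ± 0.22). Without control replicate 1 the adjusted p was 0.0708 for Itgb8, 0.0706 for Col12a1, 0.129 for Tnfrsf22 and 0.116 for Egln3; without control replicate 2 it was 0.0667 for Acta2, and without T100 replicate 1 it was 0.0567 for Il1rn. The same 6 genes were not called with the 95th percentile as a covariate, and Tpm2 was not (0.0512) without both arrays at the ends of the value range, each chosen after seeing the data. The other 10 of the 16 kept their calls without each array. Second probe sets were at 1.23 for Itgb8, 0.96 for Col12a1 and -0.56 for Tpm2, each of the same sign. Fgf19 and Tpm2 were below background at 100 µM, so the size of their falls is uncertain.

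**Figure D3:**
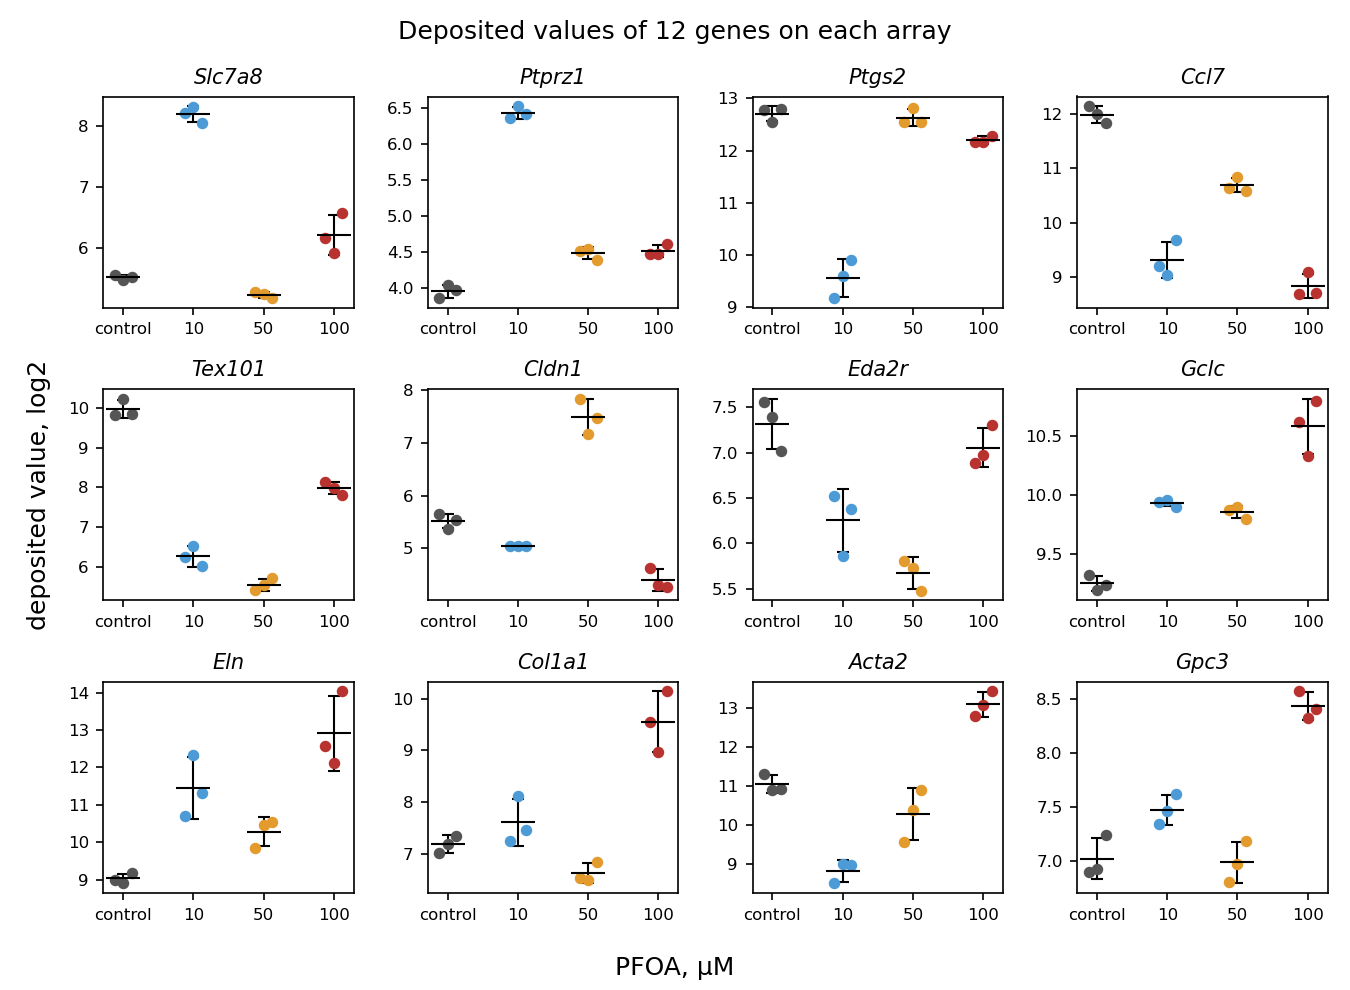
Deposited log2 values of 12 named genes on each array by group (control and 10, 50 or 100 µM PFOA), with coloured points for the 3 arrays, horizontal marks for the mean and bars for the SD. Acta2 lies at 8.84 at 10 µM, 11.05 in control and 13.09 at 100 µM.

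Of 46 genes of collagens and matrix, 3 rose at 100 µM (Eln, Col1a1 and Col12a1), 2 fell (Col8a1 and the basement membrane gene Nid2) and 41 did not pass, or 7 and 3 when adjusted over the list alone; the list did not pass camera (adjusted p = 0.104). Nid2 was named after its value was seen. Of 22 markers of stellate cells and fibroblasts (6 above background in a group), 2 rose (Col1a1 and Acta2) and 20 did not pass, with a median of -0.01 and a mean of 0.30 (camera adjusted p = 0.845). The other cell-type lists had 0 called members at 100 µM among 20 endothelial markers and 23 macrophage and leukocyte markers (camera adjusted p = 0.201 and 0.314). Each of these 2 lists had 1 member above background in a group. At 10 µM 1 endothelial marker was called lower (Tek, adjusted p = 0.108 without control replicate 1). Of the leukocyte markers, Cd3e was called lower at 10 and 50 µM.

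Some inflammatory and NF-kB genes were lower at 100 µM as well. The median change of the 39 was -0.06, with 30 lower and 9 higher. Called were 4 that fell and 0 that rose, while 35 did not pass, or 6 that fell when adjusted over the list alone. Ccl7, Il1rn, the NF-kB inhibitor Nfkbia (-0.84 ± 0.13, to below background) and Csf1 (-0.79 ± 0.15) were the 4, and the list passed camera (mean -0.24, adjusted p = 3.67e-06; adjusted p = 0.0208 with an estimated correlation). Of 37 genes of the unfolded protein and integrated stress response, Psat1, an enzyme of serine synthesis, rose (1.49 ± 0.28) and 36 did not pass, or 8 that rose when adjusted over the list alone (camera mean 0.17, adjusted p = 0.00273; adjusted p = 0.512 with an estimated correlation). Without control replicate 2 the adjusted p was 0.0577 for Nfkbia, 0.140 for Csf1 and 0.132 for Psat1. Without T100 replicate 3 the adjusted p of the stress response list was 0.0724, and with the 95th percentile as a covariate, chosen after seeing the data, it was 0.253.

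Of 38 hypoxia and glycolysis genes, Car9 rose at 100 µM, Egln3, Ndrg1 (-1.02 ± 0.14) and Adm (-0.75 ± 0.14, below background) fell and 34 did not pass, or 2 and 7 when adjusted over the list alone. Of 35 epithelial junction genes, Cldn1 (-1.11 ± 0.16, to below background), Lamb3 (-0.83 ± 0.12) and the junctional adhesion gene F11r (-0.66 ± 0.09) fell and 32 did not pass, or 1 that rose and 5 that fell when adjusted over the list alone. Camera gave an adjusted p of 0.0213 for hypoxia and 0.0269 for junction genes; with an estimated correlation the adjusted p = 0.512 and adjusted p = 0.122, and after quantile normalization neither list passed. The adjusted p of Adm was 0.0885 without T100 replicate 2 and that of Lamb3 was 0.0531 without control replicate 2. The hypoxia list lost its call without control replicate 1 (adjusted p = 0.0528), and the junction list without control replicate 2 (0.136) or T100 replicate 3 (0.0724), or with the 95th percentile as a covariate, chosen after seeing the data (0.119). Cldn1 was not called (0.0556) without both arrays at the ends of the value range, chosen likewise.

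Among 42 interferon response genes (3 above background) and 28 genes of xenobiotic metabolism (5 above background), 0 were called at 100 µM by limma, over all genes or adjusted over the list alone. Their camera adjusted p were 5.87e-04 and 0.0269, toward lower values (means -0.06 and -0.08), and with an estimated correlation the adjusted p = 0.0963 and adjusted p = 0.512; the latter list did not pass after quantile normalization, or without control replicate 1 (0.104) or T100 replicate 2 (0.0983). The members with the smallest p were Eif2ak2, a kinase activated by double-stranded RNA (-0.43 ± 0.12), and Parp14 (-0.23 ± 0.07) in the former, and Abcb1a (-0.26 ± 0.07) and Cyp3a9 (-0.36 ± 0.10) in the latter.

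Gclc, the catalytic subunit of the enzyme that limits glutathione synthesis, rose at each dose, by 0.68 ± 0.09 at 10 µM, 0.61 ± 0.09 at 50 µM and 1.33 ± 0.09 at 100 µM (2.52-fold). It was the member of the oxidative stress list, 30 genes regulated by NRF2, with the largest call at 100 µM, where 2 members rose, 0 fell and 28 did not pass, or 4 and 4 when adjusted over the list alone (camera adjusted p = 0.452). At 10 µM 1 rose and 0 fell, or 1 and 3 over the list alone. At 50 µM Gclc rose and Hmox1 fell (adjusted p = 0.136 without T50 replicate 2), or 1 and 2 over the list alone. Camera leaned toward lower values at both doses but did not pass (adjusted p = 0.0580 and 0.0970). Gpc3, an oncofetal proteoglycan, rose by 1.40 ± 0.12 at 100 µM, as 1 of 19 oncofetal genes measured, or 2 that rose and 1 that fell when adjusted over the list alone (camera adjusted p = 0.730). Without control replicate 2 the adjusted p of Gclc was 0.0629 at 10 µM and 0.0729 at 50 µM.

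**Figure D4:**
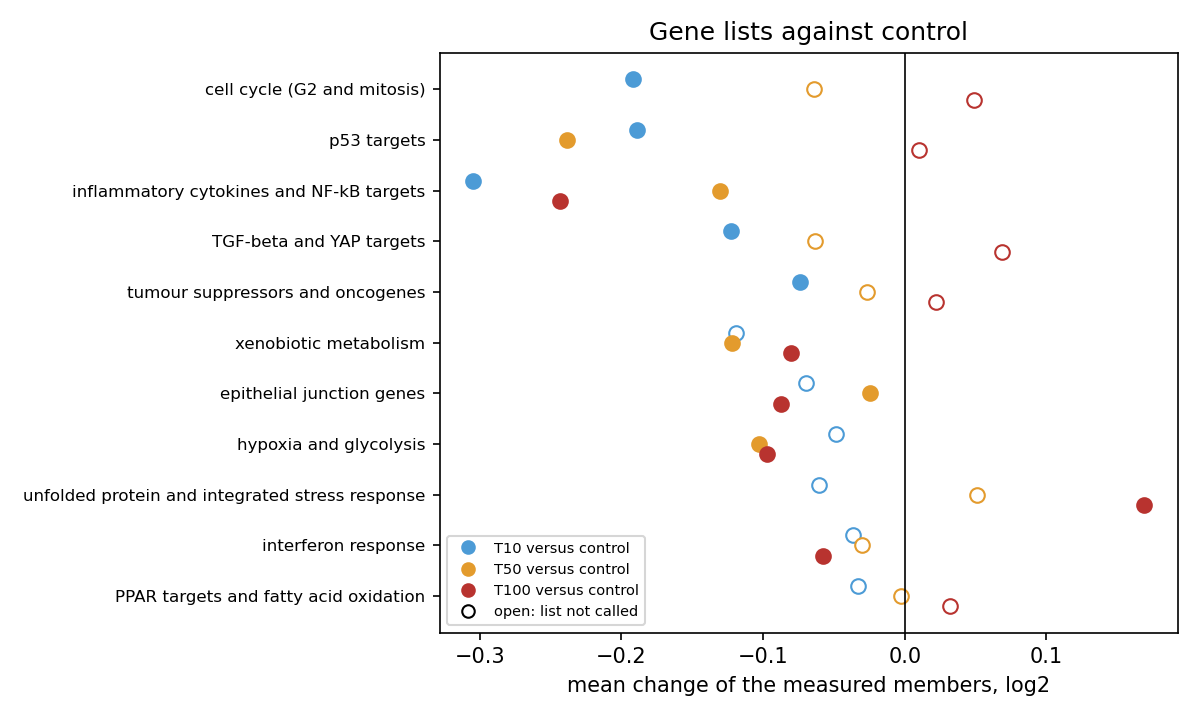
Mean log2 change against control of the measured members of each list that passed camera in at least 1 exposure, and of the PPAR list, with filled points where the list passed and open points where it did not. The inflammatory and NF-kB list lies at -0.30, -0.13 and -0.24 at 10, 50 and 100 µM. Its medians, not drawn, are -0.05, -0.02 and -0.06.

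PPAR targets and fatty acid oxidation genes, of interest because PFOA activates PPAR alpha, had few calls, and 8 of the 42 measured were above background. Called were 0 at 10 µM, where 2 fell when adjusted over the list alone, 1 at 50 µM (Ucp2, a mitochondrial carrier, -0.47 ± 0.07) and 3 at 100 µM (Ucp2, -0.52 ± 0.07, and the oxidation enzymes Decr1, 0.35 ± 0.07 and below background, and Acaa2, 0.33 ± 0.07). Adjusted over the list alone, 0 rose and 1 fell at 50 µM, and 3 rose and 1 fell at 100 µM. Camera gave adjusted p of 0.902, 0.603 and 0.201. After quantile normalization Ucp2 was at -0.13 and -0.21 and was not called, nor were Decr1 (adjusted p = 0.0602) and Acaa2 (adjusted p = 0.256). Without control replicate 2 the adjusted p was 0.148 for Decr1 and 0.153 for Acaa2 at 100 µM, and without control replicate 3 it was 0.0578 for Ucp2 at 50 µM.

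None of the 12 genes of interest measured was called by limma against control, but for Myc and Ccnd1 this depended on the processing. Myc at 10 µM was called after median centring (adjusted p = 0.0304) and without T100 replicate 1 (0.0267), and Ccnd1 was called without T50 replicate 3 at 10 µM (0.0406) and 100 µM (0.0305). Cyp4a1, Pdk4, Angptl4, Ppara, Pparg, Mmp2, Mmp9 and Cdkn1a were below background in every group, with control means of 3.53 (Mmp9) to 3.89 (Cdkn1a). Cpt1a was at -0.28 ± 0.19, -0.36 ± 0.19 and 0.39 ± 0.19 at 10, 50 and 100 µM, and the cyclin gene Ccnd1 was at 0.30 ± 0.11, 0.02 ± 0.11 and -0.31 ± 0.11. Myc was at 0.10 ± 0.08 at 50 µM and 0.05 ± 0.08 at 100 µM. Timp1, an inhibitor of matrix proteases, held 1 value on 6 of the 12 arrays, so its -0.04, -0.02 and -0.04 carry little information.

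At 100 µM 323 genes were called against control, 208 higher and 115 lower on the deposited values, and 261 higher and 260 lower after quantile normalization. At least 2-fold changes were found for 33 higher and 20 lower genes, and 214 of the 323 were above background in a group. The count was 143, 89 or 161 without control replicate 1, 2 or 3, and 156 or 193 without T100 replicate 1 or 3. With array weights it was 604, and with both arrays at the ends of the value range left out, chosen after seeing the data, it was 199. With the 95th percentile as a covariate, chosen likewise, it was 252, with 94 higher and 158 lower, so the split turned round, though all 323 kept their sign. The count of 2-fold changes went from 53 to 33, 26 or 35 without control replicate 1, 2 or 3, and to 33 without T100 replicate 1.

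The exposures were also set against each other, to see which genes depended on the dose. Between 50 and 10 µM, Ptgs2 was higher at 50 µM by 3.08 ± 0.16 (8.44-fold; adjusted p = 3.53e-05), as were Egln3 (2.56 ± 0.30), the matrix gene Fbln2 (2.49 ± 0.20) and Cldn1 (2.45 ± 0.16). Tff1, a secreted trefoil peptide, was lower by -3.57 ± 0.42 (11.9-fold; adjusted p = 0.00316), as were Slc7a8 (-2.96 ± 0.13), Vsnl1 (-2.66 ± 0.23) and Ptprz1 (-1.95 ± 0.06). Called were 443 genes, 384 higher and 59 lower at 50 µM, and 161 higher and 92 lower after quantile normalization. The count was 208 or 280 without T10 replicate 1 or 3, 265 or 191 without T50 replicate 1 or 2, and 49 (27 higher, 22 lower) with the 95th percentile as a covariate, chosen after seeing the data. Under that covariate all 443 kept their sign, the median size went from 0.42 to 0.34 and the median SE from 0.07 to 0.10, and Tff1 (adjusted p = 0.145) and Egln3 (0.142) were not called. Cldn1 at 10 µM and Slc7a8 and Ptprz1 at 50 µM were below background, so the size of these differences is uncertain.

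Between 100 and 10 µM, Acta2 was higher at 100 µM by 4.25 ± 0.30 (adjusted p = 0.000281), beside Akr1b8-ps2 (4.62 ± 1.00), Ptgs2 (2.64 ± 0.16) and Dsel (2.56 ± 0.24). Tff1 (-2.96 ± 0.42), Slc7a8 (-1.98 ± 0.13), Ptprz1 (-1.92 ± 0.06, below background at 100 µM) and Igfbp4, which binds insulin-like growth factors (-1.32 ± 0.13), were lower. Called were 681 genes, 604 higher and 77 lower on the deposited values, but 136 higher and 213 lower after quantile normalization, so the direction of the split depended on the scaling. Akr1b8-ps2 was not called after quantile normalization (adjusted p = 0.0611) or without T10 replicate 1 (0.139). The count was 246 or 325 without T10 replicate 1 or 3, 355 or 263 without T100 replicate 1 or 3, and 3 with the 95th percentile as a covariate, chosen after seeing the data. Under that covariate 672 of the 681 kept their sign, while the median size went from 0.38 to 0.25 and the median SE from 0.07 to 0.13. Of the genes named here, Acta2 (adjusted p = 0.195), Akr1b8-ps2 (0.590), Ptgs2 (0.117), Dsel (0.317), Tff1 (0.547) and Igfbp4 (0.278) were then not called, and Tff1 was not (0.0740) without both arrays at the ends of the range, chosen likewise.

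Between 100 and 50 µM, Col1a1 was higher at 100 µM by 2.93 ± 0.29 (7.60-fold; adjusted p = 0.00198), beside Acta2 (2.80 ± 0.30), Eln (2.63 ± 0.51) and Tex101 (2.44 ± 0.15). Cldn1 was lower by -3.09 ± 0.16 (adjusted p = 7.49e-05), beside Ano1 (-1.93 ± 0.11) and Fgf19 (-1.89 ± 0.31), all 3 below background at 100 µM, and the collagen-binding integrin gene Itga2 (-1.86 ± 0.33). Called were 256 genes, 145 higher and 111 lower on the deposited values, and 123 higher and 235 lower after quantile normalization. The count was 140 or 129 without T50 replicate 1 or 2, and 140 or 114 without T100 replicate 1 or 3. With the 95th percentile as a covariate, chosen after seeing the data, it was 146, with 51 higher and 95 lower; all 256 kept their sign, with a median size of 0.48 in place of 0.50, and Eln (adjusted p = 0.102), Fgf19 (0.0975) and Itga2 (0.0627) were not called. The adjusted p of Eln was 0.142 without T50 replicate 1, that of Fgf19 was 0.0867 without T100 replicate 3 and that of Itga2 was 0.102 without T100 replicate 1. Differences between exposures were not tested for the gene lists.

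Some genes with a called trend had group means in the order of dose. The trend contrast does not ask for a change at each step, and these genes were picked for ordered means. Itgb8 was 2.01 ± 0.32 above control at 100 µM (trend adjusted p = 0.0145). Col12a1 (1.69 ± 0.27) and Frmd4b (1.57 ± 0.21) were likewise higher, as was Nckap1l (1.58 ± 0.12). Nckap1l, a gene of the actin-regulating WAVE complex of blood cells, stayed below background. At 10 and 50 µM Itgb8 was at 0.16 and 0.59 and Col12a1 at 0.67 and 1.18, none of them called. The trend calls of the named genes were not tested under the other settings. Tnfrsf22 fell by 2.05 ± 0.40 (trend adjusted p = 0.0280), and Sat1, the enzyme that starts polyamine breakdown, by 1.16 ± 0.20. Socs6, a suppressor of cytokine signalling below background in every group, fell by 1.08 ± 0.08, and the carboxypeptidase gene Cpd by 0.94 ± 0.12. The trend was called for 490 genes, 365 higher and 125 lower with dose on the deposited values, and 274 and 257 after quantile normalization. For 131 of the 490 the 4 means were in order of dose, 101 rising and 30 falling. The count was 225, 167 or 247 without control replicate 1, 2 or 3, and 257 or 268 without T100 replicate 1 or 3. With the 95th percentile as a covariate, chosen after seeing the data, it was 109, with 34 higher and 75 lower, so the split turned round.

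A moderated F test found any difference among the 4 groups for 840 genes, and 507 without control replicate 2 or 551 without T100 replicate 1. The exposures shared calls. In the same direction, T10 and T50 shared 60 genes (11 higher, 49 lower), T10 and T100 shared 63 (11 and 52) and T50 and T100 shared 83 (34 and 49). Independent calls would share 0.252 higher and 0.894 lower genes for T10 and T50, 0.320 and 0.822 for T10 and T100, and 1.54 and 0.651 for T50 and T100. The comparisons use the same controls, and unchanged groups simulated with common controls, which leave out the effects, shared 0.02 higher genes on average, so this count does not show how much of the sharing comes from the controls. Across genes, which are not independent replicates, the log2 changes correlated at r = 0.423, 0.382 and 0.501 for these pairs, while common controls alone gave 0.50, 0.501 and 0.499. The covariance was 0.00838, 0.00864 and 0.0106, against 0.00357 for each pair when simulated. Shared calls ranged from 24 to 60, 19 to 55 and 23 to 79 when each array was left out in turn.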

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

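Chosen only after the result was seen were the tests of bright named genes (matched by control level in place of a first version that took all named genes over 1 level), of the chromosomes and of the stellate cell markers (with Dcn, Lum, Col1a2 and Col3a1), the fits with the range as covariate or without the arrays at its ends, as well as the 7 genes below, of which Btaf1, Lrrcc1, Rhox5, Sanbr and Serinc2 lie outside the rule for named genes.

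Genes called in opposite directions at different doses were picked by those 2 calls. A called difference between the exposures was therefore nearly fixed by the choice, and is no further support. Acta2, a contractile protein, was at -2.21 at 10 µM and 2.04 at 100 µM, a difference of 4.25 (adjusted p = 0.000281). Cldn1 was at 1.98 at 50 µM and -1.11 at 100 µM, a difference of -3.09 (adjusted p = 7.49e-05), whose size is uncertain because Cldn1 was below background at 100 µM. Rhox5, a homeobox gene of the reproductive tract, was at -0.98 at 10 µM and 0.59 at 100 µM (difference 1.58, adjusted p = 7.85e-05). Lrrcc1, a centrosomal gene, was at -0.53 at 10 µM and 0.46 at 100 µM (difference 0.99, adjusted p = 0.00110). Serinc2 was at -0.90 at 10 µM and 0.83 at 50 µM (difference 1.73, adjusted p = 0.000767). Btaf1 was at -0.19 and 0.20 at 10 and 50 µM (difference 0.39, adjusted p = 0.000767), and Sanbr at -0.20 and 0.18 (difference 0.38, adjusted p = 0.000767). The differences stayed called without each array (adjusted p of at most 0.00755), which that choice also favours. Both calls against control stayed in all 12 such fits only for Cldn1, in 9 for Rhox5, in 8 for Acta2 and in 1 or 2 for the others. After quantile normalization Btaf1 (adjusted p = 0.571), Sanbr (0.222) and Serinc2 (0.0854) were not called at 10 µM. With the 95th percentile as a covariate the differences of Acta2 (3.58, adjusted p = 0.195), Lrrcc1 (0.89, 0.301), Rhox5 (1.35, 0.0868) and Serinc2 (1.67, 0.0521) were nearly as large but not called. Under that covariate only Cldn1 kept both calls against control. At 10 µM Acta2 (0.395), Lrrcc1 (0.506), Rhox5 (0.124), Btaf1 (0.633), Sanbr (0.399) and Serinc2 (0.473) were not called. Without both arrays at the ends of the range each of the 7 genes lost at least 1 of its 2 calls against control, as Cldn1 did at 100 µM (0.0556).

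Eln, Col1a1, Col12a1 and Acta2 rose together at 100 µM against control, by a mean of 2.49. Stellate cells or fibroblasts among the cells would raise their other abundant transcripts too. The median change of all 22 measured markers was -0.00646 (quartiles -0.04 to 0.03), and Dcn and Lum stayed at 3.73 and 3.68, below background. But only 6 of the 22 were above background in a group, so the median mostly reflects dim genes and cannot exclude such cells. Among brighter markers, Col1a2 (1.25, adjusted p = 0.217) and Col3a1 (1.71, adjusted p = 0.0892) were higher but not called. Ecm1 was at -0.33, and Lox held 1 value on all 12 arrays. This explanation stays open. A wider value range on the T100 arrays would shrink the rise after quantile normalization, and the mean was then 2.46. The mean 95th percentile was 9.66 at T100 and 9.57 in control, so this setting could take little from such a rise and is a weak test. With the 95th percentile as a covariate Acta2 (adjusted p = 0.0564) and Col12a1 (0.0762) were not called, while Eln (0.0151) and Col1a1 (0.0234) were. A response of the line to the highest dose, or a subclone grown out in this culture, may also account for the rise, and the design cannot separate these because the replicates are not said to be separate cultures.

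Probe sets without a single gene symbol were not used in the report's comparisons, and many differed from control. Of 45396 such probe sets, 253 were called at 10 µM (12 higher, 241 lower), 265 at 50 µM (41 and 224) and 585 at 100 µM (117 and 468), with 179, 193 and 428 of them at least 2-fold.

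Among these, 153 probe sets were lower at all 3 doses by similar amounts (medians -1.17, -1.20 and -1.27), from a bright control level of 14.82, and after quantile normalization the medians were -0.69, -0.72 and -0.94 and 136 stayed called at 100 µM. Their names place them on 21 chromosomes. That argues against loss of 1 genomic region only if each reads the place it is named for, which was not tested here. For the 104 with enough named genes of like control level, a compression of bright signals is argued against. The median change of those genes at 100 µM was 0.0848 (quartiles 0.04 to 0.14). For the other 49, all at a control level of 16.14 or brighter, too few named genes are near, and compression stays open. They may read 1 abundant sequence: the deviations of their 138 distinct profiles within groups had a median correlation of 0.478, against 0.216 for other unnamed probe sets, below the 0.5 set beforehand for that explanation and above the 0.1 set against it. That stays open, because the probe sequences were not analysed here. A further 24, on 12 chromosomes by name, went from 9.55 in control to 4.61 and 4.70 at 10 and 50 µM and 13.42 at 100 µM. Their 20 distinct profiles had a median within-group correlation of 0.581, against 0.0662 for other unnamed probe sets. They may therefore read 1 sequence and need not be 24 separate transcripts, which was not tested. All 24 stayed called at 100 µM after quantile normalization, as did 22 of another 24 that were higher at 50 and 100 µM.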

How the results depend on the processing

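The settings with the value range as covariate, with both arrays at its ends left out, and with held genes left out, were chosen only after the result was seen; the others were planned. The median of all genes moved by less than 0.1 with either scaling, but among the 1764 genes with a mean over 8 the median at T10 was -0.07 as deposited and 0.12 after quantile normalization, so splits between higher and lower genes are only as firm as the scaling. Of 148 called results for named genes, 132 kept their call after quantile normalization, 148 after median centring, 125 with a replicate block, 92 with the range as covariate and 77 to 130 without single arrays, and 0 reversed in these. Of 16 list results, 8 kept their call after quantile normalization, 8 with fry and 1 with an estimated correlation. A replicate block gave 147, 197 and 260 genes for T10, T50 and T100 against control; same-number arrays did not pair, with 18 correlations of -0.219 to 0.112 and 4 of 12 arrays nearest one of their own number. Only 4581 genes were above background, and the ceiling hides changes in the brightest. Except where a setting tests fewer genes or arrays, the cause was not tested.

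Leaving out the dimmest 50% of genes gave 291 genes at T10, 509 at T100, 1029 between T100 and T10 and 8 lists at T50. Every probe set, named or not, gave 411, 485 and 857 against control, 201 and 394 for T50 and T100 against T10, and 761 for the trend. Quantile normalization gave 457 at T50, 521 at T100, 253 and 349 for T50 and T100 against T10, and 115, 127 and 175 shared calls for T10 with T50, T10 with T100 and T50 with T100. Array weights gave 604 at T100. Fits of only the 6 arrays compared gave 31, 110 and 93 against control, 55 and 52 against T10 and 47 for T100 against T50. With an estimated correlation 0, 0 and 1 lists passed at T10, T50 and T100, and with fry 3 at T10. The value range as covariate gave 15 at T10, 49 and 3 for T50 and T100 against T10, 146 for T100 against T50, 109 for the trend, 458 for the F test, 9 and 9 calls of T10 shared with T50 and T100, and 2 lists at T10; tumour suppressors and oncogenes there reversed to 0.0216 (adjusted p = 0.802). Without both arrays at the ends of the range, T10 gave 79, T100 199, T50 and T100 against T10 202 and 95, T100 against T50 127, the trend 264, the F test 438, and T10 shared 31 and 32 with T50 and T100.

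Without each array in turn, the counts ranged from 67 to 214 at T10, 117 to 278 at T50, 89 to 345 at T100, 191 to 431 for T50 against T10, 246 to 780 for T100 against T10, 114 to 265 for T100 against T50, 167 to 482 for the trend and 507 to 866 for the F test. Shared calls ranged from 24 to 60, 19 to 55 and 23 to 79, and lists from 4 to 9, 3 to 8 and 4 to 8.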

Other observations

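The 37 genes called at all 3 doses were mostly lower, with 30 that fell and 7 that rose on the deposited values, against 35 and 55 after quantile normalization. They were 14 to 32 without single arrays and 7 (4 lower, 3 higher) with the 95th percentile as a covariate, and part may come from the common controls. Those named here outside the rule were chosen after their values were seen, as were that covariate and both tests of held genes. Emp1, an epithelial membrane protein, rose by 0.63, 0.86 and 0.58 log2 units at 10, 50 and 100 µM, and Efna5, a ligand of Eph receptors, by 0.20, 0.37 and 0.35. Fst was at -0.63, -1.25 and -0.55, Lgmn, a lysosomal protease, at -0.67, -0.58 and -0.58, and Tex19.1, a germ-cell gene, at -0.99, -0.90 and -0.62. The NF-kB regulator Nfkbiz was at -0.92, -0.36 and -0.60, and Irak3, which restrains Toll-like receptor signals, at -0.88, -0.78 and -1.03.

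Other gene groups did not pass camera but held called members. Of 41 matrix proteases and inhibitors, 1 rose and 3 fell at 10 µM, 2 rose and 2 fell at 50 µM and 2 rose and 4 fell at 100 µM, or 1 and 7, 3 and 4, and 2 and 4 when adjusted over the list alone (camera adjusted p = 0.156, 0.152 and 0.310). Adam12 rose at each dose, while Adam19, another membrane metalloprotease, was at -1.20 ± 0.15 at 10 µM and Adam10, a sheddase, at -0.72 ± 0.12 at 100 µM. At 50 µM, 1 of 39 growth factor and feedback genes rose (Met, the receptor of hepatocyte growth factor, 0.87 ± 0.16) and 1 fell (Fgfr1, below background, -0.32 ± 0.03), or 2 and 1 when adjusted over the list alone (camera adjusted p = 0.129). Of 31 chromatin and DNA methylation genes, 1 rose at 50 µM (Ezh2, a histone methyltransferase, 0.29 ± 0.04), or 1 and 1 when adjusted over the list alone (camera adjusted p = 0.600). Of 40 oxidative phosphorylation genes, 1 rose at 50 µM (Ndufa9, 0.56 ± 0.06) and 2 rose at 100 µM (Ndufa9, 0.39 ± 0.06, and Uqcrc2, 0.19 ± 0.04, neither of them called at 100 µM after quantile normalization), or 2 at 50 µM and 3 with 1 that fell at 100 µM when adjusted over the list alone (camera adjusted p = 0.237 and 0.201). Without single arrays the adjusted p reached 0.128 for Met, 0.0749 for Adam12 at 100 µM and 0.0727 for Ndufa9 at 100 µM (control replicate 2), 0.0978 for Adam10 (control replicate 2), 0.128 for Uqcrc2 (T100 replicate 1) and 0.0657 for Ezh2 (T50 replicate 2).

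More genes fell than rose at 10 µM against control, 158 against 34. Falls among genes that hold 1 value on several arrays are argued against, since without those genes 85.3% of calls were still lower. Rises that held values hide stay open, as 547 genes not called higher hold 1 value on 3 or more of the 6 arrays. The narrower value range of the T10 arrays may contribute: 74.1% of the genes called lower rose with the 95th percentile within groups, between the 80% set beforehand for that explanation and the 60% set against it, and beside 67.6% of the genes called higher and 66.3% of all genes with a mean over 8. Quantile normalization, which equalizes the range, gave 120 higher and 121 lower, while with the 95th percentile as a covariate all 192 kept their sign, with a median size of 0.41 in place of 0.46 and a median SE of 0.10 in place of 0.07, and 15 genes in all were called (8 higher, 7 lower). The range cannot be told apart from an effect of the dose. The T10 arrays also had the highest mean 95th percentile of negative controls (5.77, against 5.42 in control), and whether this contributes was not tested.

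Other splits of the same arrays were counted for each result. For the whole design 100 splits were drawn, and 1 of them, the real one, gave as many genes: 840 in the F test against at most 139 in another split, and 490 in the trend against at most 11. Arrays grouped at random thus gave far fewer in the splits drawn, which are only a part of those possible. The counts cannot tell the compound from a difference between cultures, because the replicates are not said to be separate cultures. They say nothing on the order of the doses, because the splits broke up the replicates and any difference among the groups favours the real one. Shared calls were 60 against at most 22, 63 against 10 and 83 against 7. That shows only that the random splits drawn gave fewer. It says nothing on effects common to the doses, since regrouped arrays have few calls to share. The 6 arrays of a pair of groups allow 10 splits, too few for a share under 0.05. The real splits gave 31, 110 and 93 genes for T10, T50 and T100 against control and 55, 52 and 47 between exposures, and the highest other split gave 0 in each. For lists the real splits gave 4, 3 and 7 at T10, T50 and T100, with 9, 3 and 5 as the highest other, and 4, 4 and 1 of the 10 splits gave as many.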
